A study of Homo sapiens with 75 samples.

How the data were processed

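RNA of the human endometrial adenocarcinoma cell line Ishikawa was measured on 75 one-colour arrays, per the labels with biotin-labelled cRNA. Cells were kept overnight in phenol red-free medium with charcoal-stripped serum, which lowers the estrogen that medium and serum bring, and were then given vehicle or 17alpha-ethynyl estradiol, a synthetic estrogen. The samples make up 15 groups of 5 arrays: vehicle control and 4 doses, each collected at 8, 24 and 48 h. The very low dose was 1 pM, the low dose 100 pM and the very high dose 1 µM. The high dose is 10 nM in the treatment protocol and 1 nM in the description of the design, so doses are called by their names here and no dose-response curve was fitted on a molar scale. Each array's group and replicate number were taken from its title. Nothing in the labels says that the 5 replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

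The deposited values are intensities on a linear scale for 54675 probe sets, made with MAS5, the summarisation that compares matched and mismatched probes on each array by itself, per the submitters' processing notes. The version of MAS5, the scaling target and any detection calls or filters are not given in the sources used here. In the deposited table every array had a mean of 1500.2 after trimming 2% of its probe sets at each end, and array medians lay between 309.8 and 412.6. Intensities ran from 0.119 to 225436. Scaling each array to a common trimmed mean removes differences in overall brightness, so a change of total RNA per cell would not be seen. The arrays carry no read depth; the number of arrays limits the precision, and dim probe sets are measured against background.

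Values were used as log2(intensity + 36), where the offset is the median of the whole table divided by 10 and rounded up. A log2 change on this scale understates the change of a dim probe set. The 62 control probe sets were left out, and a probe set was tested if at least 5 arrays exceeded their own array's median, which left 34863. A limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 15 groups was fitted to all 75 arrays, with a variance trend over intensity and 60 residual degrees of freedom, and contrasts were tested two-sided with Benjamini-Hochberg adjustment over the probe sets tested in each contrast. "Called" means a limma adjusted p under 0.05. The contrasts were each dose against the control of its time, the very high minus the high and the high minus the low dose at each time, the change of the very high dose response between times, and the control at a later minus an earlier time. Errors beside log2 changes are standard errors from this fit, with 5 arrays in each group.

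Gene names come from the platform annotation given with the table. Of the tested probe sets 28517 had 1 gene symbol, 1322 had several and 5024 had none listed; 41043 of the 41097 probe sets with 1 symbol in the whole table matched the RefSeq gene table, and 0 symbols were updated. No coordinates are given, because the intensity table names no genome build. A gene was represented by its brightest tested probe set with 1 symbol, passing over those marked as cross-hybridising where another was tested, which gave 14821 genes. Genes named in the text were fixed by a rule before the data were examined: for each time the 10 largest rises and 10 largest falls called with the same sign at both the high and the very high dose, up to 4 called members of each gene list, 10 genes fixed by name including both estrogen receptors, and up to 5 genes in each direction for the other contrasts. Other genes are said to have been chosen after their values were seen, or stand as members of a fixed list. Probe sets of a named gene other than the one used did not all move: of 71 such probe sets of genes called at the very high dose at 24 h, 62 had the same sign, 35 were called and 0 were called in the opposite direction.

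The 20 gene lists were fixed at the same time: estrogen response, endometrial epithelium, steroid receptors and metabolism, DNA replication, mitosis, growth arrest, p53 and apoptosis, cholesterol synthesis, unfolded protein and amino acid stress, hypoxia and glycolysis, xenobiotic metabolism, interferon response, immediate early genes, glucocorticoid-type targets, growth factors and receptors, the Wnt pathway, ribosomal proteins, epithelial markers, fibroblast and smooth muscle markers, and immune and endothelial markers. Each was tested in the 12 dose contrasts with limma's camera at a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over all 240 pairs. Counts of members are given over all probe sets tested and adjusted over the list alone. A response score was computed per array as the mean, over probe sets called alike at the high and very high dose at the other times, of the log2 difference from the control mean, with falling probe sets turned. Scores were compared by exact two-sided permutation tests of 5 against 5 arrays, whose smallest possible p is 0.00794. Doses of a time share their control arrays, so overlaps were set beside simulated unchanged groups against shared controls, beside the count of independent lists, and beside covariances with the controls split.

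The model was tested on data simulated with the means and spreads of its fit to these arrays. Of 100 genes raised or lowered by log2 0.5 in a simulated very high dose contrast at 24 h over 34863 probe sets, 29% were called with the right sign. Of 100 changed by log2 1, 67% were. In that simulation 4 of 100 calls were false, and 0 calls fell in the 11 dose contrasts with no simulated change. Its noise was independent for each probe set and array, without shifts shared by a set of arrays. These rates therefore need not hold for the real arrays. Alternatives tried were no offset, an offset 5 times as large, no filter, quantile normalization, a fit of only the arrays of the time, the replicate number as a block (with it the high minus low dose count at 48 h was 11 in place of 4), array weights, leaving out each array of a contrast in turn and, for gene lists, the mean of all tested probe sets of a gene. Of 30 pairs of groups of a time, 1 had each same-number correlation of deviations over 0.1, control and low dose at 8 h (lowest 0.118). Their numbers lie in the same array sets, and arrays of one set with other numbers deviated together as much (mean r 0.176 against 0.176). The very low dose at 8 h has its numbers in the same sets as well. Its mean same-number r was 0.154 with the control and 0.1555 with the low dose (lowest 0.0984 and 0.065). Chosen after seeing the data were a term for 3 sets of arrays found in the data, leaving out an array that lies apart from its group, both together, the response score from probe sets of another time alone, and permutation of that score within the array sets. All arrays are kept in every result unless the sentence says otherwise.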

Results

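Gene expression was measured in Ishikawa cells, an epithelial line from a human endometrial adenocarcinoma described in the labels as carrying estrogen and progesterone receptors. The series asked how its transcripts respond to 17alpha-ethynyl estradiol at 4 doses and 3 times, with 5 arrays per group. Pearson r between arrays of a group lay between 0.917 and 0.972, and 0 pairs of arrays held identical values. On the log2 intensities, principal component 1 (16.0% of the variance) separated 48 h from the earlier times and component 3 (3.59%) separated the low, high and very high doses from the control and the very low dose. The array labelled low dose 48 h replicate 4 lay among the control and very low dose arrays of 8 h in that plot. It stayed in the analysis under its label, and counts that move by over 1.5 times without it are given both ways. After removal of the group means the arrays were divided into 3 sets of 30, 15 and 30 arrays by k-means clustering on residual components 1 and 2. The array labelled low dose 48 h replicate 4, farthest from its group mean, was left out of the clustering. It was then assigned to the set with the nearest centre. The number of sets was chosen and not tested. The split accounted for 90.9% of the variance of residual component 1 (itself 13.7%), a share that the clustering on that component in part builds in. Deviations cancel within each group, which favours an even spread of the groups over such sets. Nearly every group had 2, 1 and 2 arrays in these sets; the exceptions were the high dose at 24 h (1, 2 and 2) and at 48 h (3, 0 and 2).

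**Figure D1:**
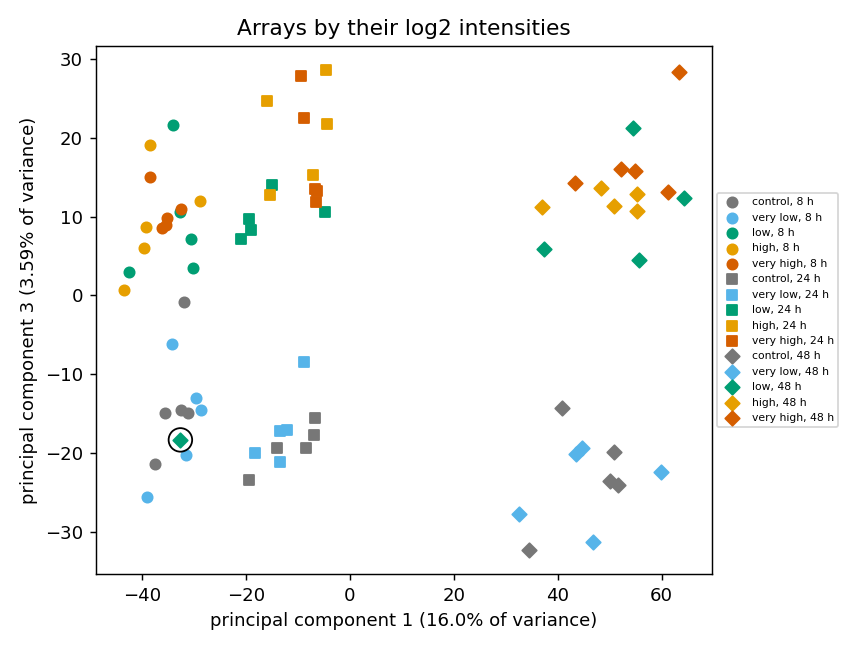
Principal component 1 (horizontal, 16.0% of variance) and component 3 (vertical, 3.59%) of log2 intensities for the 75 arrays, with colour for dose and shape for time. Low, high and very high dose arrays lie above control and very low dose arrays at each time, except for the circled array, which is labelled low dose 48 h replicate 4.

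Within 8 h of exposure the alkaline phosphatase gene ALPP (placental type, a classic estrogen-induced product of this line) rose the most. Its intensity went from 53.6 ± 26.3 in control cells to 2458 ± 245 at the very high dose (mean ± SD, n = 5), a log2 change of 4.84 ± 0.49 with a limma adjusted p of 2.14e-11. The control intensity of ALPP lay below the lowest array median (309.8) at each time, so the size of its log2 change depends on the offset. It was 5.64, 8.18 and 8.87 at 8, 24 and 48 h with no offset, and 3.50, 5.13 and 5.72 with the offset of 5 times. GREB1, a cofactor of the estrogen receptor, rose by 2.79 ± 0.26 on the log2 scale and PGR, the progesterone receptor, by 2.63 ± 0.37. The other large rises included the neurotrophic ligand NRTN (2.13), the transcription factor HES2 (2.09), the vesicle transport adaptor MLPH (2.06), the epidermal growth factor receptor ligand TGFA (1.92 ± 0.15), the mTOR inhibitor DEPTOR (1.85 ± 0.17), the Ras exchange factor RASGRP1 (1.80) and the retinal reductase DHRS3 (1.71). Falls were smaller: the phosphodiesterase PDE3A fell by 1.04 ± 0.19, the p53-inducible TP53INP1 by 0.90 ± 0.12, the repressor BCL6 by 0.80 ± 0.13, ARID5B by 0.71 and the immune checkpoint ligand VTCN1 by 0.65. TRDV3 fell by 1.11, and by 1.25 and 1.73 at the very high dose at 24 and 48 h. Its other tested probe set was not called at any of these times, nor were the other probe sets of PDE3A at 8 h.

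Of the fixed lists, estrogen response genes moved together at 8 h. At the very high dose 6 of 28 measured members rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 3.39e-17, and adjusted p = 1.86e-09 with an estimated correlation. They were GREB1, PGR, TGFA, MYC (0.77 ± 0.12), the corepressor NRIP1 (1.15 ± 0.09) and the carbonic anhydrase CA12 (1.09 ± 0.12). Immediate early genes, which growth signals induce within minutes to hours, had 6 of 22 members higher and 0 lower (8 and 0 adjusted over the list alone), with adjusted p = 6.21e-13, and adjusted p = 9.92e-05 with an estimated correlation. EGR1 rose by 1.46 ± 0.16, FOS by 1.29 ± 0.24, and the kinase phosphatases DUSP6 and DUSP5 by 0.76 and 0.60. The receptors ESR1 and ESR2 themselves were called at no dose at 8 h, with changes of -0.15 ± 0.10 and -0.25 ± 0.39 at the very high dose, nor were CCND1 (0.11), TFF1 (0.73 ± 0.30) or MKI67 (-0.04). None of these 5 was called at any dose at 24 or 48 h either.

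At 8 h limma called 249 probe sets at the low dose (163 higher, 86 lower), 378 at the high dose (215 and 163) and 316 at the very high dose (194 and 122), of which 68 at the very high dose changed over 2-fold. Genes called in the same direction at both upper doses were 91 rising and 43 falling. With the array set as a term the counts at the upper doses were 605 and 475, and within the sets of 30 arrays the very high dose called 71 and 92 probe sets. The sets were cut from the residuals of the main fit, so that term lowers the error in part by construction. The set of 15 holds 1 very high dose and 1 control array of 8 h. Its count of 7 takes the spread from 1 residual degree of freedom, that of 2 high dose arrays of 24 h, and assumes that the lone arrays vary like those.

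By 24 h ALPP stood at an intensity of 7072 ± 942 against 25.7 ± 9.35 in control cells (mean ± SD, n = 5), a log2 change of 6.85 ± 0.49. GREB1 rose by 3.63 ± 0.26, the protein phosphatase inhibitor PPP1R1A by 3.20 ± 0.45 (from a control intensity of 23.5; 4.51 with no offset and 1.76 with the offset of 5 times), MLPH by 3.06, HES2 by 2.84 and PGR by 2.62. The homeobox gene LHX4 rose by 2.33 and the metalloprotease gene TLL2 by 2.07. Falling genes now reached similar sizes to many rising ones: VWF fell by 2.01 ± 0.46 (limma adjusted p = 0.00387), the TEAD cofactor VGLL1 by 1.49 ± 0.18, PLXNA4 by 1.47, the stromelysin MMP10 by 1.43, SCUBE2 by 1.29 and the metabolic coactivator PPARGC1A by 1.25. The iron exporter SLC40A1 fell by 1.23 ± 0.12. VWF is an endothelial marker, and its control intensity here was 1250 ± 153.

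Endometrial epithelium genes at 24 h had 6 of 24 members higher and 2 lower at the very high dose, the same counts when adjusted over the list alone, with adjusted p = 1.38e-05, and adjusted p = 0.00541 with an estimated correlation. Beside ALPP and ALPG (1.98 ± 0.22), whose near-identical sequences leave open how far each probe set reads the other's transcript, the secretoglobins SCGB1D2 (1.04 ± 0.15) and SCGB2A1 (1.00 ± 0.14), the metalloprotease MMP7 (0.83 ± 0.10) and MSX1 (0.59 ± 0.05) rose. IGFBP5 fell by 1.04 ± 0.19 and the integrin gene ITGB3 by 0.98 ± 0.16. Immediate early genes stayed higher, with 6 of 22 up and 1 down (8 and 2 adjusted over the list alone; adjusted p = 1.68e-06, and adjusted p = 0.0120 with an estimated correlation): EGR1 rose by 1.08 ± 0.16 and FOS by 1.33 ± 0.24, while CCN2 fell by 0.91 ± 0.21. Estrogen response genes had 8 of 28 members higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 6.77e-11, and adjusted p = 8.89e-07 with an estimated correlation), now with RARA and SIAH2 at 0.71 each.

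Growth factors and their receptors went the other way. At 24 h 7 of 35 measured members fell and 1 rose at the very high dose (13 and 2 adjusted over the list alone), with adjusted p = 0.0194, and adjusted p = 0.0428 with an estimated correlation. With the mean of all probe sets of each gene in place of the brightest the list did not pass (adjusted p = 0.215). FGFR2 fell by 1.16 ± 0.18, FGFR3 by 0.90 ± 0.11, TGFB2 by 0.71 ± 0.10 and TGFBR2 by 0.48 ± 0.07, while TGFA rose by 2.17 ± 0.15. Of the other FGFR2 probe sets 2 fell alike at 24 h (by 1.10 and 1.09) and the rest did not pass the test. Hypoxia and glycolysis genes had 4 of 26 members higher (10 adjusted over the list alone) and 0 lower, among them EGLN3 (1.39 ± 0.21), with adjusted p = 2.40e-12, but adjusted p = 0.132 with an estimated correlation. In cholesterol synthesis INSIG1 rose by 0.62 ± 0.13 at the very high dose. The list passed at the high dose (adjusted p = 8.55e-04, and adjusted p = 0.0428 with an estimated correlation), with 2 of 19 members higher and 0 lower, or 6 and 0 adjusted over the list alone.

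At 24 h limma called 509 probe sets at the low dose (260 higher, 249 lower), 817 at the high dose (374 and 443) and 787 at the very high dose (363 and 424), 174 of the last over 2-fold. Genes called alike at both upper doses were 168 rising and 189 falling. Within the sets of 30 arrays the very high dose called 184 and 266 probe sets.

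At 48 h ALPP reached an intensity of 10510 ± 1152 against 22.5 ± 2.87 (mean ± SD, n = 5), which is below the offset of 36. The log2 change on the offset scale was 7.49 ± 0.49 for ALPP, and ALPG rose by 2.38 ± 0.22. PGR rose by 3.67 ± 0.37, MLPH by 3.55, GREB1 by 3.45, NRTN and HES2 by 2.85 each, PPP1R1A by 2.80 and the semaphorin and growth factor coreceptor NRP1 by 2.56 ± 0.35. With the offset of 5 times PPP1R1A and NRP1, both dim in control cells, changed by 1.53 and 1.66. VGLL1 fell by 2.10 ± 0.18, MMP10 by 1.93 ± 0.18, the serine protease TMPRSS2 by 1.88 ± 0.26 and SCUBE2 by 1.78. The keratin KRT23 fell by 1.64, the endothelin EDN2 by 1.58 ± 0.15 and the interferon-inducible TRIM22 by 1.37. MYC, which had risen at 8 and 24 h (0.77 and 0.74 ± 0.12), was not called at 48 h (0.17 ± 0.12). The test of the 48 minus 24 h response itself called 0 probe sets, so it did not show a loss of the MYC rise. Estrogen response genes had 5 of 28 members higher and 0 lower, and the same adjusted over the list alone (adjusted p = 6.73e-07, and adjusted p = 9.92e-05 with an estimated correlation).

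At 48 h the growth factor list had 12 of 35 members lower and 2 higher (13 and 2 adjusted over the list alone; adjusted p = 1.60e-05, and adjusted p = 2.96e-04 with an estimated correlation). FGFR2 fell by 1.55 ± 0.18, FGFR3 by 1.15 ± 0.11, TGFB2 by 1.04 ± 0.10 and TGFBR2 by 0.57 ± 0.07. EGFR, ERBB2 and FGF9 fell by 0.41, 0.31 and 0.46, and TGFA and TGFB1 rose by 2.21 and 0.65. Epithelial markers had 2 of 16 members lower and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.0324, and adjusted p = 0.0428 with an estimated correlation): KRT7 fell by 1.19 ± 0.18 and KRT8 by 0.32 ± 0.06, while the splicing regulator ESRP1 rose by 0.26. Endometrial epithelium genes had 6 of 24 higher and 3 lower (7 and 3 adjusted over the list alone; adjusted p = 1.41e-04, and adjusted p = 0.0151 with an estimated correlation), and their median change of -0.01 lay below their mean of 0.47, which includes ALPP at 7.49. SCGB1D2 rose by 1.59 ± 0.15 and IGFBP3 fell by 0.66 ± 0.13.

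Amino acid stress and unfolded protein genes were higher at 48 h at the high dose, where 10 of 27 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 4.45e-12, and adjusted p = 0.0112 with an estimated correlation). SLC7A11, a cystine importer, rose by 0.99 ± 0.19, the ATF4 targets ASNS, TRIB3 and CHAC1 by 1.05, 1.09 and 1.48, and the chaperone HSPA5 by 0.44. ASNS, TRIB3 and CHAC1 were not called in a fit of the 48 h arrays alone. At the very high dose 5 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 1.49e-07, but adjusted p = 0.0543 with an estimated correlation), and ASNS changed by 0.34 ± 0.23. The difference between these doses was itself tested and called 0 probe sets. At the low dose the list did not pass with all arrays (adjusted p = 0.191) and passed upward without the array labelled low dose 48 h replicate 4 (adjusted p = 1.76e-04, preset correlation).

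At 48 h limma called 544 probe sets at the low dose (243 higher, 301 lower), 1152 at the high dose (523 and 629) and 1156 at the very high dose (429 and 727), 214 of the last over 2-fold. Genes called alike at both upper doses were 188 rising and 269 falling. Without the array labelled low dose 48 h replicate 4 the low, high and very high dose called 827, 1387 and 1343. A fit of only the 48 h arrays, in which that array has a larger share of the spread, called 255, 595 and 578 at the 3 doses. Within the sets of 30 arrays the very high dose called 257 and 407 probe sets.

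**Figure D2:**
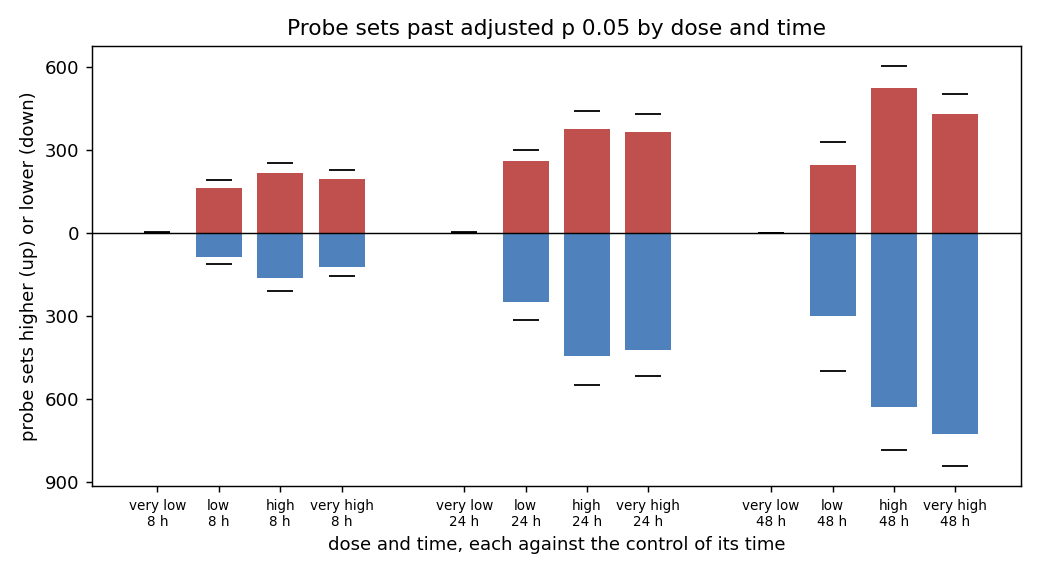
Number of probe sets past a limma adjusted p of 0.05 at each dose against the control of its time, with higher probe sets drawn upward and lower ones downward from 0; bars use all 75 arrays and short lines give the counts without the array labelled low dose 48 h replicate 4. The very low dose called 0 at each time with all arrays, and the very high dose called 316, 787 and 1156 at 8, 24 and 48 h.

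Over all 20 lists and 12 dose contrasts, 67 of 240 tests passed with the preset correlation and 37 passed with an estimated correlation as well. Estrogen response genes passed upward in 10 of 12 contrasts (9 in both tests), endometrial epithelium in 9 (6), immediate early genes in 6 (5), and steroid receptors and metabolism in 1 (1). Endometrial epithelium passed upward at 8 h with median changes of -0.046, 0.039 and -0.074 at the low, high and very high dose. The test weighs the mean of a list, so these passes do not show that most members rose. Growth factors and receptors passed downward in 7 (7), epithelial markers in 4 (4) and the Wnt pathway in 2 (1), with FRZB at -1.22 ± 0.33 at the very high dose at 48 h. Among cell cycle lists, mitosis genes passed upward in 7 and downward in 1 (1 in both tests, at the low dose at 48 h), with median changes of 0.13 and 0.12 at the low and high dose at 24 h. DNA replication passed upward in 3 (0) and growth arrest upward in 1 (0). At the low dose at 48 h these tests weakened without the array labelled replicate 4. The preset adjusted p went from 5.82e-10 to 3.11e-05 for mitosis and from 2.67e-08 to 0.0244 for DNA replication, and 0 members of either list were then called there. With all arrays, 0 of 36 mitosis genes were called at the very high dose at each time, while CENPE (-0.58 ± 0.16) was lower at the high dose at 8 h and TPX2 (0.32 ± 0.09) and TTK (0.28 ± 0.06) were higher at 48 h at the low and the high dose. Of 40 DNA replication genes GINS1 (0.33) was higher at the low dose at 24 h. At 48 h ORC1 (0.68 and 0.63 ± 0.17) and RFC3 (0.39 and 0.43 ± 0.11) were higher at the low and high dose. At the very high dose RFC3 (0.44 ± 0.11) was higher and GINS3 (-0.51 ± 0.15) lower at that time. Adjusted over the list alone, 6 genes of each list rose at the low dose at 48 h, and 2 mitosis and 5 DNA replication genes rose at the high dose. At the high dose at 48 h 2 genes of each list were higher without the array labelled low dose 48 h replicate 4. Xenobiotic metabolism passed upward in 2 (1), cholesterol synthesis upward in 2 and downward in 1 (1), stress genes upward in 2 (1), hypoxia and glycolysis upward in 4 and downward in 2 (0) and ribosomal proteins upward in 3 (0). The 3 passes of ribosomal proteins ended with quantile normalization (adjusted p = 0.890, 0.439 and 0.476). With the mean of all probe sets of each gene, growth factors did not pass at the low dose at 8 h or at the high and very high dose at 24 h (0.343, 0.0580 and 0.215). Nor did the Wnt pathway at the very low and very high dose at 48 h (0.176 and 0.0556). Without the array labelled low dose 48 h replicate 4 the downward pass of hypoxia genes at the low dose at 48 h ended and turned upward (adjusted p = 0.303). The pass of xenobiotic metabolism genes at the high dose at 48 h ended as well (adjusted p = 0.0641). Beside the stress genes, 5 tests then passed that had not. They were steroid receptors and metabolism (up, 0.0267), ribosomal proteins (up, 0.0220) and epithelial markers (down, 0.0260) at the low dose at 48 h, hypoxia at the high dose at 48 h (down, 0.0292) and growth arrest at the very high dose at 24 h (up, 0.0328). The lists for p53 and apoptosis, interferon response, glucocorticoid-type targets, fibroblast and smooth muscle markers, and immune and endothelial markers passed in 0 contrasts, with smallest camera adjusted p of 0.335, 0.289, 0.0747, 0.191 and 0.491.

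At the very low dose limma called none of the marker genes at any time. ALPP changed by 0.28 ± 0.49, -0.02 and -0.02 at 8, 24 and 48 h, PGR by 0.08, -0.11 and 0.02 (SE 0.37), and GREB1 by 0.37, 0.19 and 0.00 (SE 0.26), with 5 arrays per group. With all arrays limma called 0 probe sets at each time, with 1239, 894 and 1099 of the 34863 at an unadjusted p under 0.05, below the 1743 that chance gives. The array sets and the array labelled low dose 48 h replicate 4 stay in the error of this fit. A count below chance is therefore no sign that the dose had no effect. At 48 h limma called 1 without very low dose replicate 1. The gene nearest to a call at 24 h was DEPTOR, chosen after its values were seen, at 0.65 ± 0.17, 0.82 ± 0.17 and 0.41 ± 0.17 at the 3 times (adjusted p = 1, 0.280 and 1). Without the array labelled low dose 48 h replicate 4, whose deviation widens the shared error of such genes, DEPTOR was called at 8 h (SE 0.10, adjusted p = 2.08e-04) and 24 h (SE 0.10, adjusted p = 1.28e-07), and it was the 1 probe set called at each. Lists that passed at this dose with the preset correlation were all lost with an estimated one: cholesterol synthesis at 8 h (adjusted p = 0.206 with an estimated correlation), estrogen response at 24 h (0.126), hypoxia at 24 and 48 h (0.487 and 0.609), mitosis at 48 h (0.349) and the Wnt pathway at 48 h (0.0543).

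Summed over responsive genes, the very low dose differed from the control at 24 h. Over 825 probe sets called alike at both upper doses at 8 or 48 h, the mean response at the very low dose at 24 h was 0.0457 ± 0.0195 on the log2 scale (SD, n = 5), 7.79% of that at the very high dose, and 5 of 5 arrays lay above all controls (exact permutation p = 0.00794, adjusted 0.00952 over 12 tests). That adjustment is mild, because every test of the low, high and very high dose among the 12 also gave the smallest possible p. At 8 h the response at the very low dose was 0.0120 ± 0.0167 (exact p = 0.230) and at 48 h 0.0258 ± 0.0220 (exact p = 0.0556). Within the 3 array sets the difference from the control was 0.0312, 0.0785 and 0.0436 at 24 h, 0.0235, 0.0024 and 0.0054 at 8 h and 0.0345, 0.0366 and 0.0118 at 48 h, above 0 in each. An exact two-sided permutation within the sets, chosen after seeing the data, allows 72 arrangements. The exact p was 0.0278 at 24 h, the smallest it can give, 0.139 at 8 h and 0.0833 at 48 h (adjusted 0.0833, 0.139 and 0.125 over the 3 times). A single time at the smallest p cannot pass this adjustment.

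The low dose already gave most of the response. ALPP rose by 4.42, 6.35 and 5.69 (SE 0.49) at 8, 24 and 48 h, GREB1 by 2.83, 3.23 and 2.35 (SE 0.26), PGR by 2.43, 2.32 and 2.62 (SE 0.37), and DEPTOR by 1.84, 1.97 and 1.39 (SE 0.17). Without the array labelled low dose 48 h replicate 4 the 48 h values were 7.03 ± 0.16 for ALPP, 2.97 for GREB1, 3.32 for PGR and 1.80 for DEPTOR. The mean response at the low dose was 89.7%, 89.5% and 70.9% of that at the very high dose at the 3 times, and 87.0% at 48 h without that array. The high dose exceeded the low dose by 0.0235 at 8 h (exact permutation p = 0.0714), by 0.0562 at 24 h (exact p = 0.00794, adjusted 0.0143) and by 0.175 at 48 h (exact p = 0.00794), or 0.0630 without that array at the same p. The very high dose exceeded the high dose by 0.0279 at 48 h (exact p = 0.00794), while at 8 and 24 h the differences of 0.0134 and 0.00544 did not pass (exact p = 0.175 and 0.635).

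Gene by gene these steps were mostly below what limma calls. The very high minus high dose contrast called 0 probe sets at 8, 24 and 48 h (1365, 1034 and 1350 at an unadjusted p under 0.05), and the high minus low dose contrast called 0, 0 and 4 (1793, 1282 and 2440). The 4 were EPRS1 (0.41) and CRISPLD1 (0.49), with CCDC71L (0.72) and IGFBP3 (-0.53) through other probe sets and chosen after their values were seen. That count of 4 was 0 without the array labelled low dose 48 h replicate 4 and 76, 16, 64 and 75 without replicates 1, 2, 3 and 5 of that group. It was 1 and 11 without high dose 48 h replicates 3 and 5. The counts of 0 became 4 for very high minus high at 8 h and 1 at 24 h without high dose replicate 5 of that time. At 48 h they became 2 and 1 without very high dose replicates 4 and 2 and 1 without high dose replicate 4. For high minus low at 8 h the count became 1 without high dose replicate 3 or 5.

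**Figure D3:**
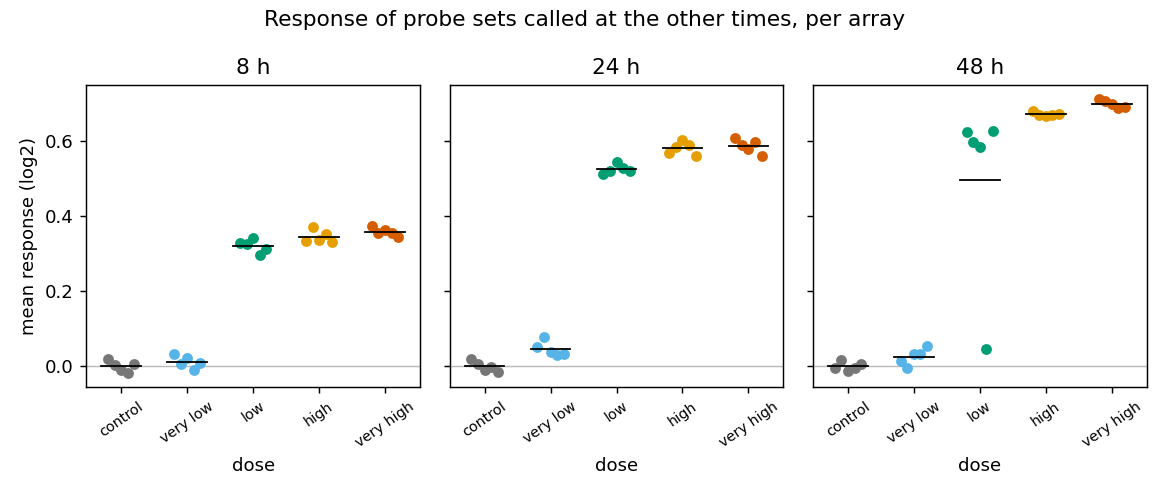
Mean log2 response per array (points; horizontal lines are group means of 5 arrays) at each dose, for 978, 825 and 645 probe sets called alike at the high and very high dose at the other times. Group means at the very low dose are 0.0120, 0.0457 and 0.0258 at 8, 24 and 48 h against 0.357, 0.586 and 0.698 at the very high dose, and the point at 0.045 in the low dose 48 h group is replicate 4.

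**Figure D4:**
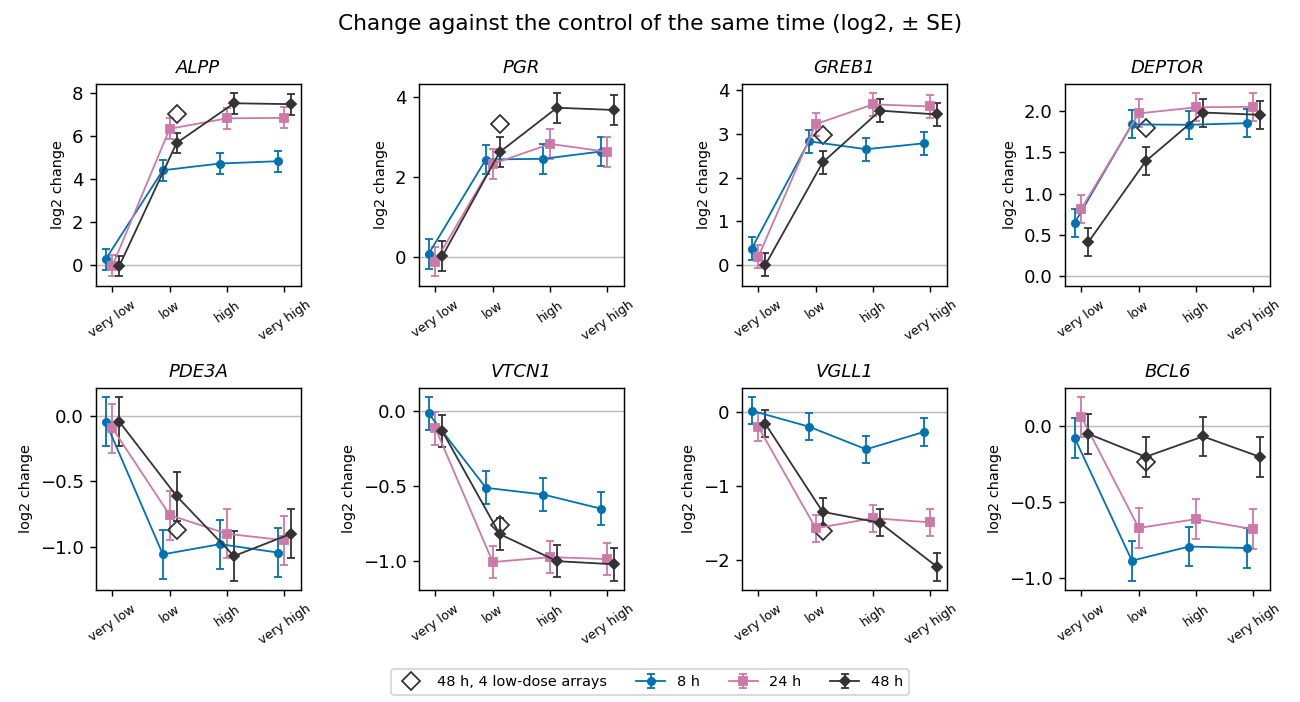
Log2 change against the control of the same time (vertical; error bars are SE) at each dose (horizontal) for 8 genes at 8, 24 and 48 h; open diamonds give the low dose at 48 h without the array labelled replicate 4. At the low, high and very high dose ALPP, PGR, GREB1 and DEPTOR rise and PDE3A, VTCN1, VGLL1 and BCL6 fall, except that limma did not call VGLL1 at 8 h, BCL6 at 48 h or PDE3A at the low dose at 48 h.

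The same probe sets recurred across doses and times. At 8, 24 and 48 h 227, 596 and 758 probe sets were called alike in the high and very high dose, where independent lists would share 1.77, 9.28 and 19.6, and 201, 431 and 414 were called alike in the low and very high dose. The 414 at 48 h was 645 without the array labelled low dose 48 h replicate 4. With only the 48 h arrays it was 215, and the 758 was 418. In 0 cases were directions opposite. These contrasts share controls. Simulated unchanged groups against shared controls had 0 calls in both, with noise drawn independently for each probe set and array, unlike that of the real arrays. At 48 h the covariance of high and very high dose changes over all probe sets was 0.0737 against 0.0392 simulated, an excess of 0.0344. It was 0.0339 with the controls split between the doses. Between times, which share no arrays, the very high dose called 220 probe sets alike at 8 and 24 h (3.50 for independent lists), 452 at 24 and 48 h (13.3) and 205 at 8 and 48 h (4.93), again with 0 opposite.

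The response to the very high dose changed with time for a smaller group of genes. Between 8 and 24 h limma called 6 probe sets: the response of the mitochondrial carboxylase subunit PCCA grew by 1.09 ± 0.19, the carbonic anhydrase CA2 by 0.96 ± 0.12 and the creatine kinase CKB by 0.92 ± 0.16. The stress gene DDIT4 went from -0.48 at 8 h to 0.14 at 24 h (difference 0.63 ± 0.12), PROM1 changed by -0.41 ± 0.08, and the last was a further probe set of CAPS (1.17), chosen after its values were seen. Between 8 and 48 h it called 69 (31 higher, 38 lower). Without the array labelled low dose 48 h replicate 4, which is in neither contrast but widens the shared error, these counts were 16 (12 higher, 4 lower) and 118 (47 and 71). The change at the very high dose grew by 1.64 ± 0.31 for ALPG, by 1.41 ± 0.24 for OLFML3 and by 1.28 for CAPS. That of ACP3 went from -0.77 ± 0.21 at 8 h to 0.70 ± 0.21 at 48 h (difference 1.47) and that of EML6 from -0.42 to 0.72 (difference 1.14). VGLL1 changed by -1.83 ± 0.26, EDN2 by -1.39 ± 0.21, MMP10 by -1.26 ± 0.26 and the hedgehog inhibitor HHIP by -1.16 ± 0.24. Between 24 and 48 h 0 passed (1679 at an unadjusted p under 0.05). A fit of only the arrays of the times compared called 26 in place of 6 and 29 in place of 69, and lost MMP10.

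Control cells changed with time in culture as well. From 8 to 24 h the dioxin-inducible CYP1A1 fell by 1.68 ± 0.26 (intensity 2236 ± 141 to 681 ± 146, SD, n = 5), CYP1B1 by 1.21 ± 0.14, CA2 by 1.44 ± 0.08 and MON1A by 1.25, and the glycolytic regulator PFKFB4 rose by 1.34 ± 0.24. From 24 to 48 h the hypoxia-inducible NDRG1 rose by 1.91 ± 0.31, DUSP4 by 1.80 and FBXO17 by 2.07, while MYEOV fell by 1.99 ± 0.16, CHAC2 by 1.72 ± 0.22 and NEURL3 by 1.69 ± 0.20. limma called 532 probe sets in the first step (332 higher, 200 lower) and 5793 in the second (2914 and 2879). The ACTB RNA quality ratio given below also differed between the control groups of 24 and 48 h. RNA quality was thus not separated from time in culture in the second step. The count of 532 was 319 without control 24 h replicate 5, 332 and 330 without control 8 h replicates 1 and 2, 328 and 342 without control 24 h replicates 2 and 4, and 917 without the array labelled low dose 48 h replicate 4.

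No dose group differed from the control of its time in an RNA quality test after adjustment. The log2 ratio of the 3' to the 5' control probe sets ran from -0.233 to 0.0334 for GAPDH and from -0.0611 to 0.404 for ACTB over the 75 arrays. Of 12 dose groups against their controls 0 passed for GAPDH (smallest exact permutation p = 0.278) and 1 had an unadjusted p under 0.05 for ACTB (0.0238, adjusted 0.286). The smallest p such a test of 5 against 5 arrays can give is 0.00794, so 1 group alone at that p would not pass adjustment over 12 tests. Times were not compared in these tests. The control means at 8, 24 and 48 h were 0.0873, 0.0274 and 0.215 for ACTB and -0.086, -0.083 and -0.123 for GAPDH.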

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

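Chosen only after the result was seen were the tests on the array labelled low dose 48 h replicate 4 (except the count without it), on the 3 array sets and on the stress genes, the splits without that array and the arrays that large splits put together. Groups of 5 arrays were searched for an array far from the rest in intensity, RNA quality, response and named genes; chance marks about 1 in 20 such groups, and 23 of 275 were marked where chance gives 13.8.

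The array labelled low dose 48 h replicate 4 lay far from its group in response (0.045) and in log2 intensity of PGR (6.999), GREB1 (8.30), ALPP (6.18), MYC (12.44) and CCND1 (15.03). Its ACTB ratio of 0.0918 lay inside the range of the other arrays, which argues against low RNA quality, and on an axis from the 8 h (0) to the 48 h control mean (1) its nearest 48 h array of the same set was 0.758 away, which argues against its array set. Its own position was 0.0352, inside the 8 h range of -0.0485 to 0.0717, so a sample exchanged with or labelled for another time and dose may explain it; 0 arrays labelled 8 or 24 h lay beyond 0.5, so no partner was found among these 75. Without it the low dose at 48 h called 827 probe sets in place of 544 and the high dose 1387 in place of 1152, so the gap went from 608 to 560, and with 4 arrays at each dose it was 313 to 416, which argues against this array as the whole cause of the gap. No biological explanation was tested for the array's place.

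Clustering of the residuals into 3 sets put 2, 1 and 2 arrays in them from all groups but the high dose at 24 and 48 h. A technical step done in sets could leave such a mark, and control transcripts added at the bench, which no cell makes, were compared between sets. Their median range was 0.791 of a within-set SD, with 28 of 42 under 1 SD, the bound set for arguing against such a step, and 3 over 2 SD (highest 3.29). All 3 read the same added transcript, cre, and were brightest in 1 of the sets of 30 arrays. For the highest the log2 mean was 16.45 there, against 16.2 in the other set of 30 and 16.04 in the set of 15. The highest intensity of an array ran from 164187 to 225436 there, against 116642 to 165357 and 126230 to 163923. The test was read as open because of the 3 probe sets over 2 SD, a reading made after the values were seen. Under the median alone it would count against the step. Whether the sets were separate cultures, labelling or scans cannot be told apart, since the labels name no such step.

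Amino acid stress genes were higher at the high dose at 48 h, with a mean log2 over all 27 measured list members of 13.55 ± 0.11 against 13.15 ± 0.15 in control (SD, n = 5). Without its 2 highest arrays the group still lay 0.334 ± 0.096 (SE) above the control mean, which argues against 1 or 2 arrays carrying it. The change was 0.492 ± 0.119 and 0.247 ± 0.131 within the 2 sets holding both groups, and since the smaller is under 2 SE a part of the array sets in it stays open, although with the set as a term the list passed (camera adjusted p = 1.79e-11). The means were 13.21 ± 0.15 and 13.39 ± 0.22 at the very low and very high dose and 13.21 ± 0.27 at the low dose, or 13.32 ± 0.09 without the array labelled replicate 4 there (n = 4), and control 48 h replicate 2 (13.41) lay above high dose 48 h replicate 5 (13.38). A response to estrogen stays open as a hypothesis, and so does the state of the medium at 48 h, which was not tested.

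Other arrays far from their group were high dose 24 h replicate 5 (median intensity 405) and low dose 24 h replicate 5 (median 309.8, and TFF1 at 8.00 log2). The GAPDH ratio stood apart in low dose 24 h replicate 1 (-0.172), low dose 48 h replicate 1 (-0.107) and very high dose 48 h replicate 3 (-0.0471), and the ACTB ratio in very low dose 8 h replicate 2 (0.385). High dose 8 h replicate 1 lay 85.4 from its group mean. On the log2 scale, ESR1 was 12.78 in control 8 h replicate 5, ESR2 6.99 in control 48 h replicate 2, ALPP 11.03 in low dose 8 h replicate 1 and 11.51 in very high dose 8 h replicate 4, and CCND1 14.13 in high dose 48 h replicate 3. Among very high dose arrays, VAV3 was 11.75 in 8 h replicate 5, LHX4 9.94 in 24 h replicate 3, SCUBE2 6.82 in 48 h replicate 1 and EDN2 9.70 in 48 h replicate 4.

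The response to the very high dose differed between times by a test of the difference itself. Between 8 and 24 h limma called 6 probe sets, among them PCCA (1.09), CA2 (0.96), CKB (0.92), DDIT4 (0.63) and PROM1 (-0.41; not called without control 8 h replicate 1, at -0.37). Between 8 and 48 h it called 69, among them ALPG (1.64), ACP3 (1.47), OLFML3 (1.41), CAPS (1.28), EML6 (1.14), VGLL1 (-1.83), KRT23 (-1.41), EDN2 (-1.39), MMP10 (-1.26) and HHIP (-1.16). KRT23 was near the threshold (adjusted p = 0.0496) and was not called in 16 of 20 fits that left out an array. Without the array labelled low dose 48 h replicate 4 the counts were 16 and 118.

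The groups were also split anew 100 times for each count. In the contrasts listed first the real split alone, 1 of 100, reached the count, which argues against a chance arrangement of these arrays. The splits were not adjusted over the counts. They cannot test chance differences between cultures if arrays of a group share a culture. At 8 h the low, high and very high dose called 249, 378 and 316 (highest other split 24, 45 and 30). At 24 h they called 509, 817 and 787 (67, 138 and 128). At 48 h the high and very high dose called 1152 and 1156 (295 and 326). The 24 minus 8 h and 48 minus 8 h responses had 6 and 69 (1 and 1), and the control steps 532 and 5793 (12 and 2235). For the low dose at 48 h the real split did not stand alone: 7 of 100 splits called 544 or more. The real low dose contrast called 863 with the set as a term. The highest of the other splits, at 1367, put 4, 1 and 0 arrays of the 3 sets against 0, 1 and 4. The other 5, at 557 to 1017, put the array labelled low dose 48 h replicate 4 with 4 controls. Without that array the 827 stood alone (highest other 511). Nor did the 4 of high minus low dose at 48 h stand alone, since 20 of 100 splits reached it. The highest, at 1989, put 5, 0 and 0 arrays against 0, 1 and 4. The real contrast called 56 with the set as a term and 0 without the array labelled low dose 48 h replicate 4. Counts of 0 from limma are reached by 100 of 100 splits: for the very low dose at 8, 24 and 48 h the highest other split was 9, 1 and 11 (1239, 894 and 1099 probe sets at an unadjusted p under 0.05), for very high minus high 1, 6 and 52 (1365, 1034 and 1350), for high minus low at 8 and 24 h 4 and 2 (1793 and 1282), and for the 48 minus 24 h response 1 (1679).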

How the results depend on the processing

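Chosen after seeing the data were the array set term, leaving out the array labelled low dose 48 h replicate 4, and both together. The array sets were cut from the residuals of the main fit, so their term lowers the error in part by construction. Over all alternatives run, 0 called values of named genes reversed. Apart from leaving out each array in turn, 54 counts of changed probe sets moved by over 1.5 times and 176 did not, and 13 counts of probe sets called alike moved and 74 did not. Signal over background limits dim genes, and a change of log2 0.5 was called for 29% of simulated genes. Over the 30 pairs of groups the replicate numbers do not pair the samples (mean r of same-number deviations 0.0123, lowest -0.220, other numbers -0.00272; 24.7% of arrays matched their own number best). Exceptions were the control, low and very low dose at 8 h, whose numbers lie in the same array sets. Mean same-number r was 0.176 for control and low dose, where each number lay above 0.1. It was 0.154 for control and very low dose (lowest 0.0984) and 0.1555 for low and very low dose (lowest 0.065). At the low dose at 8 h the block gave 262 in place of 249. The replicate block moved high minus low dose at 48 h from 4 to 11 and no other count by over 1.5 times. Except where fewer arrays or the wider spread from 1 array explain it, the cause was not tested.

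High minus low dose at 48 h (4) was 21 with no offset, 18 with the offset of 5 times, 2 with no filter and 8 with quantile normalization; with no offset very high minus high at 48 h was 1 in place of 0. With only the arrays of the time the very low dose at 24 h called 1, the low, high and very high dose at 48 h 255, 595 and 578, high minus low at 48 h 0, the 24 minus 8 h and 48 minus 8 h responses 26 and 29, and the control step from 8 to 24 h 1072; alike at 48 h were 418 in high and very high and 215 in low and very high. With limma array weights the very low dose called 2 at 8 h and 1 at 24 h, the very high dose at 8 h 540, the low dose at 24 h 899, high minus low 1 at 8 h and 1 at 48 h, very high minus high at 48 h 2, the 24 minus 8 h and 48 minus 8 h responses 21 and 129, and the control step 1199; 666 were alike in low and very high at 24 h.

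With the array set block the high and very high dose at 8 h called 605 and 475, the low dose at 48 h 863, high minus low at 48 h 56, the 24 minus 8 h and 48 minus 8 h responses 10 and 109, and the control step from 8 to 24 h 1072. Leaving out the array labelled low dose 48 h replicate 4 gave 1 and 1 at the very low dose at 8 and 24 h, 827 at the low dose at 48 h, 0 for high minus low at 48 h, 16 and 118 for the 24 minus 8 h and 48 minus 8 h responses, 917 for the control step and 645 alike in low and very high at 48 h. Both together gave 1 and 2 at the very low dose at 8 and 24 h; 458, 830 and 599 at the low, high and very high dose at 8 h, 914, 1495 and 1407 at 24 h and 1206, 1984 and 1988 at 48 h; 2 for high minus low at 48 h; 32, 8 and 221 for the 24 minus 8 h, 48 minus 24 h and 48 minus 8 h responses; and 1658 for the control step. Alike in high and very high were then 413, 985 and 1254 at 8, 24 and 48 h, in low and very high 353, 719 and 905, and at the very high dose 370, 768 and 347 between 8 and 24, 24 and 48, and 8 and 48 h. List tests past the threshold were 67, and 37 with an estimated correlation. With the mean of all probe sets of a gene there were 59. Lost were growth factors at the low dose at 8 h and the high and very high dose at 24 h, endometrial epithelium at the low and epithelial markers at the very high dose at 8 h, estrogen response at the very low and growth arrest at the high dose at 24 h, and the Wnt pathway at the very low and very high dose and xenobiotic metabolism at the high dose at 48 h. Gained were immediate early genes at the very low dose at 24 h and epithelial markers at the low dose at 48 h. There were 68 with quantile normalization (6 lost, 7 gained), 66 with no offset (1 lost), 69 with the replicate block (1 lost, 3 gained), 69 with the array set block (2 lost, 4 gained) and 71 without the array labelled low dose 48 h replicate 4 (2 lost, 6 gained).

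Leaving out each array of a contrast in turn gave 0 at the very low dose at 8 and 24 h, and 0 to 1 at 48 h (1 without its replicate 1). The low, high and very high dose gave 186 to 215, 285 to 370 and 263 to 284 at 8 h, 393 to 474, 670 to 759 and 654 to 762 at 24 h, and 465 to 827 (without the array labelled replicate 4), 950 to 1114 and 955 to 1094 at 48 h. Very high minus high gave 0 to 4 at 8 h (without high dose replicate 5), 0 to 1 at 24 h (without high dose replicate 5) and 0 to 2 at 48 h (2 without very high dose replicate 4, 1 without its replicate 2 or high dose replicate 4). High minus low gave 0 to 1 at 8 h (without high dose replicate 3 or 5), 0 at 24 h and 0 to 76 at 48 h. There it was 0 without low dose replicate 4, 76, 16, 64 and 75 without low dose replicates 1, 2, 3 and 5, and 1 and 11 without high dose replicates 3 and 5. The 24 minus 8 h response gave 5 to 9, the 48 minus 24 h response 0 and the 48 minus 8 h response 46 to 69. The control steps gave 319 to 452 and 4781 to 5728; the lower of the former were 319, 328 and 342 without control 24 h replicates 5, 2 and 4, and 332 and 330 without control 8 h replicates 1 and 2.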

Other observations

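The test of the very low dose shift and that of culture time were set before their results were seen; the response from probe sets of 1 other time and the calls without the array labelled low dose 48 h replicate 4 were chosen after, as was the permutation within array sets.

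Beyond the comparisons above, the transcription factor CEBPD rose at the very high dose by 0.72, 0.82 and 0.82 ± 0.13 at 8, 24 and 48 h, and the apoptosis gene PMAIP1 by 0.98 ± 0.20 at 24 h. In xenobiotic metabolism GCLC, a subunit of the enzyme that starts glutathione synthesis, rose by 0.59 ± 0.09 at 48 h. The smooth muscle marker TAGLN fell by 0.79 ± 0.18 at 48 h. CA2 fell in control cells from 8 to 24 h (-1.44 ± 0.08) while its change at the very high dose grew from 1.13 to 2.08. These values share the control arrays, so the fall in control cells by itself adds to that growth.

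The very low dose may shift estrogen-responsive genes by amounts mostly below the reach of single probe sets in the main fit. DEPTOR was an exception in other fits. It was called at 8 and 24 h without the array labelled low dose 48 h replicate 4 (0.645 and 0.819). With all arrays and array weights it was called at both times too (0.644 and 0.782, limma adjusted p = 0.0251 and 9.20e-05). TGFA was called at 24 h with the array set term and without low dose 48 h replicate 4 (0.37 ± 0.072, limma adjusted p = 0.0413). PACRGL, chosen after its values were seen, was called at 8 h with array weights (1.109 ± 0.213, limma adjusted p = 0.0334). The mean response had its smallest exact two-sided permutation p of 0.00794 at 24 h (5 of 5 arrays above all controls), the smallest p this design can give, against 0.230 and 0.0556 at 8 and 48 h. With probe sets of 1 other time alone the unadjusted p was 0.00794 from either at 24 h, 0.0238 from those of 8 h and 0.0556 from those of 24 h at 48 h, and 0.286 and 0.119 from those of 24 and 48 h at 8 h. Permuted within the 3 array sets, the p was 0.0278 at 24 h, the smallest of 72 arrangements, and 0.139 and 0.0833 at 8 and 48 h. None passed once adjusted over the 3 times (0.0833 at 24 h). A single time at that smallest p cannot pass this adjustment, so the adjusted value at 24 h decides nothing. Whether the shift differs between times was not tested.

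Estrogen could move genes the way that 24 to 48 h in culture does. Of the 316 probe sets called at the very high dose at 8 h, 48.1% moved in the same direction in control cells from 24 to 48 h (46.4% of rising and 50.8% of falling ones), which argues against a shared direction with that step. Of all tested probe sets 53.4% rose in it. Among probe sets called in both, 41 moved in the same and 58 in the opposite direction. The step from 8 to 24 h was not tested in this way.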
